A study of Mus musculus with 2 samples.

How the data were processed

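The series holds 2 droplet single-cell RNA libraries (10x Genomics) of AB2.2 mouse embryonic stem cells that had been differentiated toward mesendoderm for 4 days, 1 library of wild type cells and 1 library of PHD2 knockout cells. AB2.2 is an established mouse embryonic stem cell line. PHD2 is the oxygen-sensing prolyl hydroxylase encoded by Egln1. Per the labels' protocol, cells were brought into suspension with trypsin before library preparation. Both groups were taken from the sample titles. With 1 library per group no test between the groups was possible, and neither p-values nor standard errors are given.

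The authors deposited 1 matrix per library of whole-number counts of unique molecular identifiers (UMIs) per gene and cell barcode. The matrices were written by Cell Ranger 4.0.0, per the file headers. The submitters' processing notes name the mm10 genome build, Cell Ranger and Seurat. Sequencing depth, the transcript end that was read, and the part of Egln1 that was altered are not given in the sources used here. The counts are not normalized, and both libraries list the same 27998 genes. The wild type matrix held 9651 barcodes and 226179474 UMIs, and the PHD2 knockout matrix held 7713 barcodes and 173470962 UMIs.

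Cells were kept with at least 1000 genes detected and at most 10% of UMIs from mitochondrially encoded genes. Of the wild type barcodes 391 were below the gene limit and 157 above the mitochondrial limit, and of the knockout barcodes 298 and 150 were. Scrublet, run in each library alone through scanpy, marked 4 wild type cells (0.0434%) and 0 knockout cells at its automatic threshold, which is below the 0.5% taken as a working call. The cells with the highest doublet scores were therefore removed up to 0.8% per 1000 barcodes, which took out 712 wild type cells (7.72%) and 456 knockout cells (6.18%). This left 8515 wild type cells with a median of 20431 UMIs and 3576 genes, and 6927 knockout cells with a median of 20999 UMIs and 3854 genes. Doublets that these scores miss remain among the kept cells.

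UMIs were summed over the kept cells of each library (201448584 and 157750409 UMIs) and scaled to the total of the library (CPM). The log2 ratio is knockout over wild type with a pseudocount of 1 CPM, which understates the change of low genes. Each level has an exact Poisson interval and each fold an exact conditional binomial (Clopper-Pearson) interval, both at 95%. These intervals and those of shares cover counting error only and say nothing about the spread between cultures or clones. Across 38 gene lists fixed before the data were examined, a member was called measured at 5 CPM or more in the higher library, and higher or lower where its levels differed by at least 1.5-fold. A list median has an order-statistic interval over its members (their range for fewer than 6) and a percentile among 10000 random lists of the same size, matched on mean expression in 20 bins. That percentile describes these 2 libraries and is not a p-value. The 8540 genes at 5 CPM or more had a median log2 ratio of 0.16, so a list median of that size is no difference from other genes. The percentile among matched random lists is given for the lists the text dwells on, and not for every list. Of the list and marker genes, 2 (Rian and Zscan4a) were not found under their symbols.

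Both libraries were clustered together on 2000 highly variable genes scaled to 10000 counts per cell, 30 principal components, 15 neighbours and Leiden resolution 1. HIF targets, glycolysis genes, mitochondrially encoded, ribosomal protein and Y-linked genes, Xist and Egln1 were left out of the clustering genes. Clusters were named from markers of 16 classes fixed before the data were examined. The rule that turns markers into names was set after the data were seen: at least 3 markers at 10 CPM or more and over 2-fold above all other cells, no other class with more markers among the 10 leading genes, and at least 3 markers in each library that gives 20 cells and 5% or more of the cluster. Levels within a class were computed where each library had at least 200 cells. For shares of cells with a UMI, every cell was thinned at random to 14000 UMIs, which left out 778 wild type and 646 knockout cells that were shallower.

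The text names genes by a rule fixed before the data were examined: genes of the oxygen-sensing pathway, the 10 highest and 10 lowest log2 ratios among genes of at least 50 CPM in the higher library (mitochondrially encoded, ribosomal protein and predicted genes left out), up to 2 members from each end of a list with its most abundant member, the 5 highest and 5 lowest genes within a class, the genes of the shares, and cluster markers. Some genes that the rule takes are not reported here. Other genes are named as chosen after their values were seen. Gene coordinates come from the GENCODE M21 annotation of mm10, matched on Ensembl gene identifiers for 27645 genes.

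Alternatives fixed beforehand were no limits on cells, stricter limits (2000 genes, 5% mitochondrial UMIs), doublets kept, median-of-ratios size factors, totals without mitochondrially encoded and ribosomal protein genes, a mean over cells, pseudocounts of 0.1 and 5 CPM, other floors for lists (none, and 20 CPM), other clustering settings and another thinning depth. Clustering without the markers and splits by chromosome 8 share were added after the data were seen, as were 3 gene lists. The level and list steps were tested on simulated libraries with the real totals: 100% of 94 genes changed 2-fold, 98.98% of 98 genes changed 1.6-fold and 0% of 5778 unchanged genes passed the 1.5-fold rule, and 95.8% of the ratio intervals of 6161 genes held the true ratio. The simulated counts held counting error only, with no spread between cultures or clones. These values therefore check the computation and give no rate of false calls for the real libraries. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9.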

Results

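Single-cell transcriptomes were compared between wild type and PHD2 knockout AB2.2 mouse embryonic stem cells after 4 days of differentiation toward mesendoderm, the common precursor state of mesoderm and endoderm. Each group was 1 library, so the differences have no replicate check. The wild type library gave 8515 kept cells with a median of 20431 UMIs, and the PHD2 knockout library gave 6927 kept cells with a median of 20999 UMIs. Levels are UMIs summed over the kept cells of a library and scaled to its total (CPM), with 95% intervals for counting error only.

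The first comparison asked how far the targeted gene and its pathway differed. Egln1 (ENSMUSG00000031987; mm10 chromosome 8, 124908587 to 124949324, minus strand), which encodes PHD2, was at 18.2 CPM in wild type cells (95% interval 17.6 to 18.8) and 13.6 CPM in knockout cells (13.1 to 14.2), 1.33-fold lower in the knockout (1.26 to 1.41). The altered part of the gene is not given in the sources used here, and UMIs from transcript outside that part would remain, so this level does not check the knockout. Egln1 was 1.79-fold lower in knockout cells with a high share of chromosome 8 UMIs (18.5 against 10.4 CPM) and within counting error in cells with a low share (16.2 against 17.6 CPM), a split made after the data were seen. Egln3, a hydroxylase gene that is itself induced by hypoxia-inducible factor (HIF), was 3.25-fold higher in the knockout (1.89 against 6.15 CPM; interval of the fold 2.89 to 3.67). Hif1a was at 38.3 and 48.8 CPM, Egln2 at 36.3 and 40.1 CPM, Vhl at 3.95 and 5.08 CPM, Hif1an at 7.67 and 10.0 CPM, Arnt at 6.63 and 8.40 CPM and Hif3a at 2.93 and 2.29 CPM in wild type and knockout cells. Epas1 stayed at 0.159 and 0.260 CPM, from 32 and 41 UMIs.

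HIF targets were higher in the knockout library. Of 18 measured members 11 were higher, 0 were lower and 7 lay between, and their median log2 ratio was 0.78 (0.23 to 1.01), at percentile 100 of matched random lists, whose median was 0.20. Ddit4, an inhibitor of mTORC1 signalling, was at 17.2 CPM in wild type and 51.5 CPM in knockout cells, and P4ha1, a collagen prolyl hydroxylase, at 2.66 and 9.44 CPM. Stc2 (15.6 and 11.1 CPM), Vegfa (6.87 and 6.14 CPM) and Higd1a (311 and 288 CPM) did not share that direction. Of 14 measured glycolysis genes 5 were higher and 0 lower, with a median of 0.46 (-0.07 to 0.98) at percentile 100. Ldha, which makes lactate from pyruvate, was 2.19-fold higher (687 against 1506 CPM) and Pfkl, a phosphofructokinase, was at 26.0 and 61.5 CPM, while Gapdh was at 4370 and 4367 CPM, Hk2 at 33.9 and 31.9 CPM and the lactate transporter Slc16a3 at 73.3 and 63.4 CPM. With median-of-ratios size factors the median of all genes moved from 0.16 to -0.08, and the medians of HIF targets and glycolysis were 0.56 and 0.22.

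None of the 28 nuclear oxidative phosphorylation genes passed 1.5-fold, and their median was -0.03 (percentile 74.2), with Sdha at 54.4 and 68.3 CPM, Uqcrq at 920.5 and 749 CPM and Cox8a at 1523 and 1471 CPM. The 12 measured mitochondrially encoded genes had a median of 0.36 (percentile 100), none past 1.5-fold, with mt-Co3 at 1319 and 1910 CPM. Among 10 measured genes of collagens and their hydroxylases 4 were higher and 1 lower (median 0.44, percentile 98.7), and Col18a1 was at 44.3 and 24.3 CPM.

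The second comparison asked how far differentiation had gone in each library. Genes of the primitive streak, the site where the embryo's mesoderm and endoderm arise, and of the nascent mesoderm had the highest list medians. Mesp1, a transcription factor of the earliest mesoderm (chromosome 7, 79792241 to 79793788), was at 0.402 CPM in wild type and 220 CPM in knockout cells, a ratio of 548 (441 to 690). T, the Brachyury gene (chromosome 17, 8434423 to 8442496), was 54.3-fold higher (51.3 to 57.6; 5.86 against 318 CPM), and Mixl1 (chromosome 1, 180693043 to 180697034) was at 0.948 and 73.2 CPM, a ratio of 77.2 (67.0 to 89.6). The wild type levels of Mesp1 and Mixl1 rest on 81 and 191 UMIs and may include background. Neither ratio therefore fixes the size of the difference in expression, and the intervals cover counting error only. Within cells of a low share of chromosome 8 UMIs the Mixl1 ratio was 59.9 (45.8 to 80.1). Upp1, Ifitm1, Sp5, Fst, Peg3 and Fgf8 were also among the 10 highest ratios. Of these Ifitm1 was at 50.2 and 466 CPM, the follistatin gene Fst at 33.6 and 228 CPM, the Wnt-responsive factor Sp5 at 8.89 and 75.6 CPM and the uridine phosphorylase gene Upp1 at 11.4 and 158 CPM in wild type and knockout cells. T was also higher within cells of a low share of chromosome 8 UMIs (9.79 and 351 CPM) and within those of a high share (5.14 and 291 CPM), as was Mesp1 (0.711 and 341 CPM, and 0.346 and 119.7 CPM).

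The 10 lowest ratios were those of Pou3f1, Utf1, Ppp1r1a, Fgfbp1, Slc7a3, Myl9, Sfn, Gng3, Tagln and Hmox1. Pou3f1, a factor of the formative epiblast, was 4.22-fold lower in the knockout (90.3 against 21.4 CPM; 4.07 to 4.38), and Utf1, a chromatin factor of pluripotent cells, 4.09-fold lower (424 against 104 CPM; 4.02 to 4.16). The amino acid transporter Slc7a3 was at 65.9 and 25.6 CPM, stratifin (Sfn) at 544 and 229.9 CPM, the contractile genes Myl9 and Tagln at 96.9 and 40.0 CPM and at 789 and 415 CPM, and the haem oxygenase gene Hmox1 at 282 and 149 CPM.

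By list, 10 of 12 measured primitive streak genes were higher and 0 lower in the knockout, with a median of 2.37 (1.45 to 4.84; percentile 100). Nodal (61.7 and 68.4 CPM) and Fgf17 (9.60 and 10.2 CPM) were the exceptions, and Eomes, a factor of mesendoderm, was at 12.0 and 49.7 CPM. All 7 measured nascent mesoderm genes were higher (median 2.98, 0.74 to 7.30; percentile 100), from Cyp26a1, which degrades retinoic acid (0.159 and 26.8 CPM), to Lefty2 (8.06 and 14.2 CPM) and Phlda2 (163 and 455 CPM). Of 6 measured lateral and extraembryonic mesoderm genes 5 were higher (median 2.33), with Tbx3 at 0.869 and 12.9 CPM and Gata6 at 0.174 and 5.79 CPM. Etv2 and Lmo2, factors of the blood and endothelial lineages, were at 11.2 and 50.1 CPM and at 1.29 and 6.99 CPM. Cdx2, Nkx1-2 and Greb1 of the caudal list were all higher (median 1.75, percentile 99.9), with Cdx2 at 1.30 and 16.4 CPM. The 5 measured definitive endoderm genes were higher (median 1.34, percentile 99.95), but 2 of them, Gsc (0.417 and 19.96 CPM) and Gata6, also belong to mesendoderm or mesoderm lists, and the endoderm factors Sox17 and Foxa2 were at 0.313 and 0.482 CPM and at 0.104 and 0.621 CPM.

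General pluripotency genes had a median of -0.36 (-0.96 to 0.01; percentile 0), with 1 of 12 higher and 4 lower. Gdf3 was at 35.6 and 10.1 CPM, Pou5f1 (Oct4) at 143 and 113 CPM and Sox2 at 38.4 and 25.1 CPM, while Tdgf1, the Nodal co-receptor, was at 168 and 311 CPM. Formative and primed epiblast genes went both ways (2 higher and 4 lower of 11, median -0.30, percentile 0.01): Fgf5 was at 10.3 and 22.1 CPM and Zic2 at 15.9 and 26.5 CPM. The 11 measured naive pluripotency genes had a median of 0.25 (percentile 68.4), with Zfp42 at 20.8 and 34.3 CPM, Nanog at 35.1 and 45.5 CPM, Spp1 at 35.4 and 15.4 CPM and Dppa5a at 595 CPM in both libraries.

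**Figure D1:**
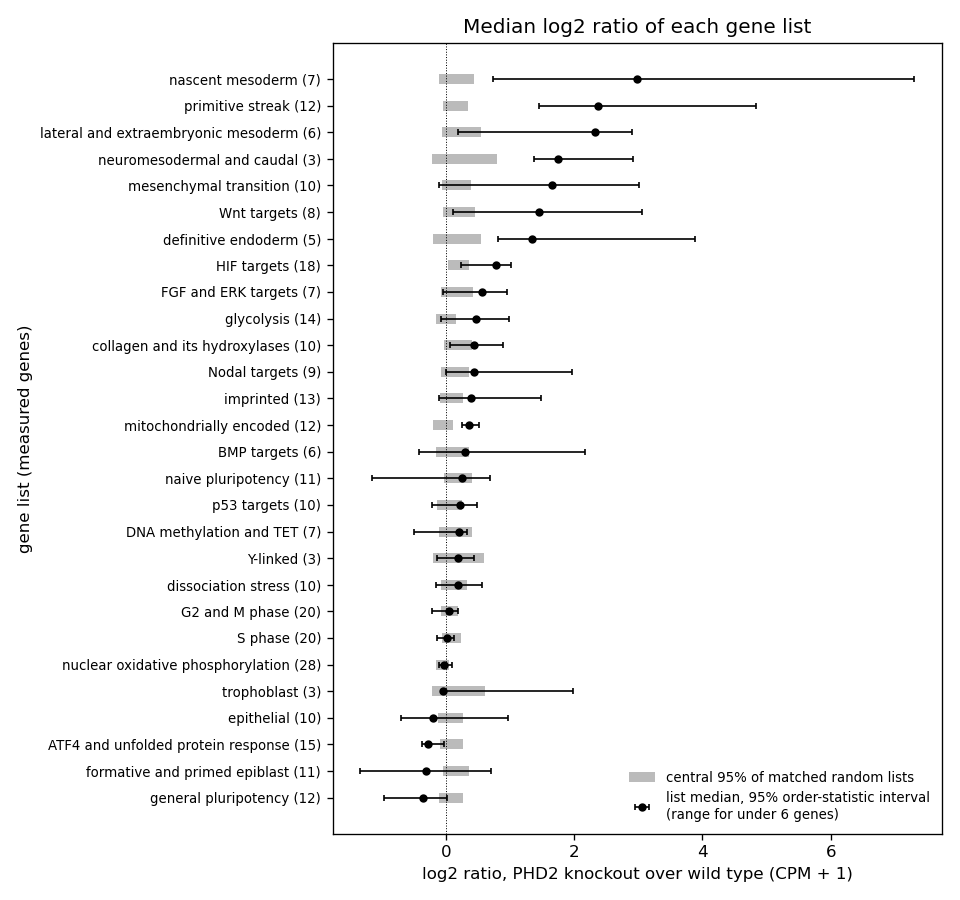
Median log2 ratio (x axis, knockout over wild type, pseudocount 1 CPM) of each gene list that was fixed before the data were examined and had at least 3 measured genes, with the order-statistic interval over its members; grey bars give the central 95% of matched random lists. Nascent mesoderm (2.98) and primitive streak (2.37) lie highest and general pluripotency (-0.36) lowest.

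Of the signalling lists, Wnt targets were mostly higher (7 of 8; median 1.46, percentile 100), with Dkk1 at 0.258 and 9.509 CPM and Ccnd1 at 69.4 and 74.8 CPM. Nodal targets had a median of 0.43 (4 of 9 higher, percentile 99.5), with Lefty1 at 43.4 and 43.6 CPM. The 4 higher ones, Eomes, Gsc, Lefty2 and Tdgf1, also belong to the primitive streak, nascent mesoderm or general pluripotency lists. Sp5 of the Wnt list and Msx2 of the BMP list are likewise shared with streak or mesoderm lists. The signalling lists are therefore not separate evidence from those. FGF and ERK targets had a median of 0.57 (4 of 7 higher, percentile 99.8), with Dusp6 at 22.5 and 44.5 CPM. BMP targets had a median of 0.29 (2 of 6 higher, percentile 93.0), with Msx2 at 1.85 and 11.9 CPM and Id1 at 448 and 534 CPM. Genes of the mesenchymal transition were higher in 6 of 10 cases (median 1.66, percentile 100), with N-cadherin (Cdh2) at 1.95 and 24.2 CPM and vimentin (Vim) at 87.3 and 342 CPM, whereas Sparc was at 209 and 160 CPM. Epithelial genes had a median of -0.20 (2 higher and 2 lower of 10, percentile 0.27), with Dsp at 13.1 and 46.8 CPM and Crb3 at 60.7 and 35.1 CPM. The imprinted list had 6 higher and 2 lower of 13 (median 0.39, percentile 99.95), with Peg3 at 33.1 and 166 CPM and Grb10 at 40.9 and 16.4 CPM.

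Among cycle genes, none of 20 S phase genes (median 0.01) and none of 20 G2 and M phase genes (median 0.04) passed 1.5-fold. Both medians lay below the 0.16 of all measured genes, which is not matched on expression. That does not show that cycle genes were lower than genes of like expression. Targets of ATF4 and the unfolded protein response had a median of -0.28 (percentile 0), with 2 of 15 lower, Chac1 at 56.5 and 33.3 CPM and Trib3 at 39.4 and 24.8 CPM. Medians were 0.23 for p53 targets, 0.19 for dissociation stress, 0.20 for DNA methylation and TET genes and 0.20 for Y-linked genes, and each of these 4 changed sign with median-of-ratios size factors. The trophoblast list had 3 measured members, with Peg10 at 17.3 and 71.6 CPM and a median of -0.05 that changed sign under other settings. Fewer than 3 members were measured in the remaining lists, among them Hoxb1 (0.293 and 19.1 CPM) in neuroectoderm, Dll3 (4.75 and 15.8 CPM) in paraxial mesoderm, Wnt6 (6.69 and 28.1 CPM) in surface ectoderm, Myl7 (4.28 and 8.44 CPM) in the cardiac list, Dnd1 (7.24 and 27.6 CPM) in germ cells, Cdh11 (0.119 and 7.13 CPM) in feeder fibroblasts and Rhox5 (6.88 and 10.5 CPM) in visceral endoderm. The node and 2-cell-like lists had 0 measured members.

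To compare how many cells carried these transcripts, every cell was thinned to 14000 UMIs. A T UMI was found in 6.46% of 7737 wild type cells (5.93 to 7.03, exact binomial) and 81.5% of 6281 knockout cells (80.5 to 82.4). Without thinning the shares were 10.1% and 86.1%. Mixl1 was found in 1.27% and 38.6% of thinned cells, Mesp1 in 0.569% and 33.1%, Eomes in 13.6% and 35.9%, Fgf5 in 11.7% and 21.4%, Zfp42 in 20.7% and 30.3% and Nanog in 35.2% and 39.8%. Sox2 was found in 37.5% and 20.7%, and Pou5f1 in 85.7% and 75.2%. Sox17, Foxa2, Sox1 and Pax6 each stayed under 1% in both libraries. As a background, the same shares were taken in naive pluripotent-like cells, a type that should lack these genes, thinned to the same depth. They were 2.62% of 343 wild type and 47.2% of 339 knockout cells for T, 0.875% and 6.79% for Mixl1, 0.583% and 15.9% for Mesp1 and 8.75% and 16.8% for Eomes. The wild type shares of Mesp1 and Mixl1 were not clearly above those of this class. Those rest on few of its 343 wild type cells and cannot show that expression is absent. Wild type Mixl1 was at 1.71 CPM (1.28 to 2.24) in cells of low chromosome 8 share and 0.948 CPM (0.818 to 1.09) over all cells. Its signal was thus not an even background. In knockout cells of that class T stood at 25.7% of its level over all knockout cells (23.8 to 27.6), Eomes at 31.8%, Mixl1 at 9.03% and Mesp1 at 5.45% (4.46 to 6.58), which are not in the 1 ratio that a single source of free RNA would keep.

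**Figure D2:**
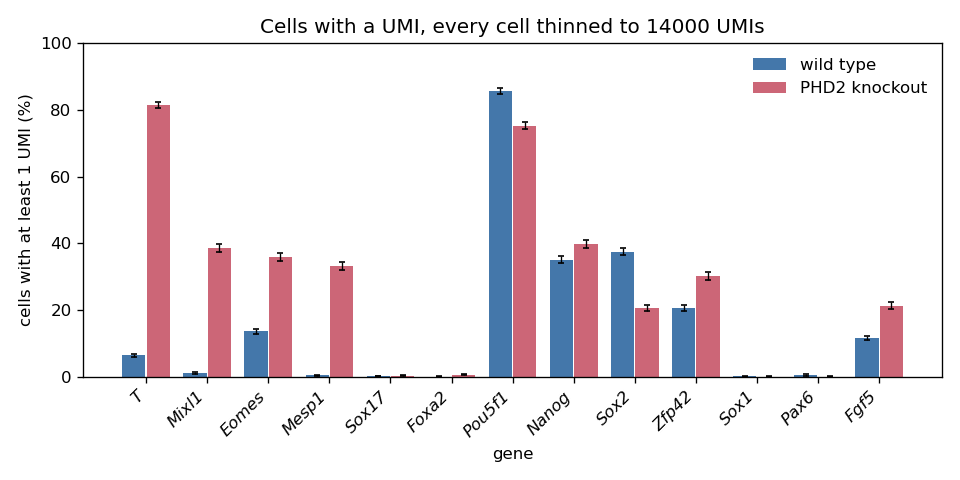
Share of cells with at least 1 UMI (y axis, percent) for 13 genes (x axis) after every cell was thinned to 14000 UMIs; bars are the 2 libraries and error bars exact 95% binomial intervals. T was found in 6.46% of wild type and 81.5% of knockout cells, and Pou5f1 in 85.7% and 75.2%.

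Clustering gave 17 clusters, most of them nearly all from 1 library, and a cluster mostly of 1 library may be that library, not a type. A mesoderm-like cluster, named from Mesp1, Cyp26a1, Gata6 and Pmp22 among its leading genes, held 1081 of 6927 knockout cells (15.6%, 14.8 to 16.5) and 0 of 8515 wild type cells, which allows a share of up to 0.0352% (3 counts of the total). When all markers were left out of the clustering genes it held 1064 knockout cells (15.4%) and 0 wild type cells. It held 2 wild type cells with 15 components and 1 with stricter limits on cells, and could not be named with no limits on cells. Primitive streak-like clusters, led by T and Fgf8 and also by the immune genes Psmb8 and, in the larger of them, Isg15, held 3489 knockout cells (50.4%) and 36 wild type cells (0.423%), but the knockout share ranged from 16.6% to 63.1% over the other settings that named such a cluster, and none was named when each library was clustered alone. With the markers left out of the clustering genes they held 47.9% of knockout and 0.458% of wild type cells. A haemato-endothelial-like cluster led by Lmo2 and Etv2 held 123 knockout cells (1.78%) and 15 wild type cells (0.176%), and could not be named under 4 other settings. Zscan4-expressing 2-cell-like cells made up 0.846% of wild type and 0.679% of knockout cells. Unnamed clusters held 94.1% of wild type and 26.4% of knockout cells, the latter up to 77.5% under other settings, including a shallow cluster with mesoderm markers that the naming rule kept out of the mesoderm class (0.634% of wild type and 2.71% of knockout cells). The naming rule compares a cluster with all other cells. A state spread over most of a library can therefore stay unnamed, above all with each library alone. Named and unnamed shares thus depend partly on that rule.

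Naive pluripotent-like cells, named from Klf2 and Dppa5a among the leading genes, made up 4.45% of wild type cells (379; 4.02 to 4.91) and 5.14% of knockout cells (356; 4.63 to 5.69), and were the 1 named class with at least 200 cells in each library. Within it HIF targets had a median of 0.45 (0.30 to 0.69; 6 of 16 higher, 0 lower; percentile 99.99) and glycolysis genes 0.54 (0.34 to 0.71; 6 of 15 higher, 0 lower; percentile 100). Egln1 was at 10.95 CPM (8.86 to 13.4) in wild type and 5.60 CPM (4.16 to 7.39) in knockout cells of the class. Levels in this class were not corrected for free RNA, which at the upper bound of the Mesp1 ratio (6.58%) would give T 20.9 CPM in its knockout cells. Primitive streak genes had an uncorrected median of 1.06 (8 of 10 higher), and the highest ratios included those of T (1.96 and 81.7 CPM), Upp1 (15.3 and 67.7 CPM), Sccpdh and Peg10. The lowest were those of Myl9 (55.2 and 18.0 CPM), Pou3f1 (58.4 and 20.1 CPM), Tagln, Tpm2 and Cdkn1c (64.1 and 33.4 CPM). General pluripotency genes had a median of 0.07 there, against -0.36 over all cells.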

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

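Of 835 alternative values for 98 results, 615 stayed within the interval of the value as reported, 220 moved and 0 called values changed sign. Splits by chromosome 8 share and clustering without markers were chosen after the data were seen. The sign changed for Egln1, Egln2 and Epas1 and for 9 list medians, each under 1.5-fold as a log2 ratio with its pseudocount (Epas1, from 32 and 41 UMIs, was over it as a plain ratio), and for no other named gene or list median. The medians of HIF targets (0.45 to 0.84) and glycolysis (0.22 to 0.54) stayed above 0 under every alternative. The Egln1 log2 ratio of -0.39 became -0.62 with median-of-ratios size factors, 0.11 in cells of low and -0.78 in cells of high chromosome 8 share. Within naive pluripotent-like cells the medians were 0.072 for general pluripotency, 1.06 for primitive streak and 0.37 for nascent mesoderm, where 3 mesoderm genes were measured. For these and the changes below the cause was not tested.

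The naive pluripotent-like share of wild type cells was 5.41% at resolution 0.6, 6.74% at 1.4, 5.67% with Leiden seed 2, 5.26% with each library alone, 5.45% thinned, 6.30% with doublets kept, 2.11% with no limits on cells and 6.78% with stricter limits. In knockout cells it was 5.69% at resolution 1.4, 5.76% with seed 2, 4.35% with each library alone, 3.14% with no limits and 5.999% with stricter limits, so the order of the libraries depended on the setting. The primitive streak-like share of wild type cells was 0.176% at resolution 1.4, 0.223% with 15 components, 0.0822% with all variable genes, 0.207% thinned, 0.271% with doublets kept and 1.28% with no limits. In knockout cells it was 44.6% at resolution 0.6, 18.95% at 1.4, 43.4% and 43.0% with seeds 1 and 2, 32.9% with 15 components, 16.6% with all variable genes, 47.9% without markers, 22.6% thinned, 42.0% with doublets kept, 63.1% with no limits and 43.0% with stricter limits. The mesoderm-like share of knockout cells was 18.6% with 15 components, 17.1% thinned, 17.1% with doublets kept and 17.8% with stricter limits. No mesoderm-like cluster could be named with no limits on cells, no primitive streak-like cluster with each library alone, and no haemato-endothelial-like cluster at resolution 0.6, with 15 or 50 components or with no limits. Unnamed clusters held 57.1% of knockout cells at resolution 1.4, 60.2% with all variable genes and 77.5% with each library alone. Thinned, an epiblast-like class was named as well, with 18.8% of wild type and 1.15% of knockout cells.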

Other observations

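The tests on library scaling, on HIF targets by chromosome 8 share, on the held-out side of chromosome 8 and on UMIs per cell were set down before their results were seen, and the tests on Egln1 and primitive streak genes by chromosome 8 share, on HIF targets in low-share against high-share cells and on thinned shares after. For 3 gene lists chosen after the data were seen, the values describe genes picked for their difference and are not independent evidence of it. Of 13 measured interferon response and antigen processing genes 7 were higher in the knockout library, 0 lower and 6 between (median log2 ratio 0.68, against 0.16 for matched random lists), with the immunoproteasome gene Psmb8 at 15.4 and 66.2 CPM and the guanylate-binding protein gene Gbp2 at 5.86 and 29.3 CPM in wild type and knockout cells. NF-kB targets had a median of 0.82 (6 of 8 higher), with the chemokine gene Ccl20 at 2.40 and 17.1 CPM. Within naive pluripotent-like cells the interferon list had a median of -0.16. Actin cytoskeleton and SRF targets had a median of -0.70 (7 of 13 lower, 0 higher), with Acta2 at 20.1 and 3.55 CPM and Actb at 2220 and 2224 CPM. An unnamed cluster led by Ccl20, Lgals3 and Krt19 held 12.1% of knockout and 0.153% of wild type cells, and an unnamed cluster led by Acta2, Cryab and Tagln held 20.5% of wild type and 1.75% of knockout cells.

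An unnamed cluster shared by both libraries (286 wild type and 261 knockout cells) was led by the endoplasmic reticulum chaperone genes Sdf2l1, Derl3 and Hspa5. Without correction for free RNA, T within it was at 2.07 and 176 CPM and Fgf8 at 22.4 and 234 CPM in wild type and knockout cells. In another shared cluster (263 and 223 cells) T was at 7.90 and 108 CPM, the keratin gene Krt8 at 163 and 528 CPM and Lefty1 at 172 and 50.6 CPM, while Eomes was at 6.41 and 6.50 CPM. HIF targets went both ways in that cluster, by genes chosen after their values were seen. Ddit4 was at 43.8 and 87.1 CPM, Stc2 at 7.26 and 1.93 CPM and Slc2a1 at 31.0 and 31.5 CPM. Ldha was at 562.5 and 703 CPM there, against 587 and 1490 CPM in the chaperone-led cluster. The difference in these genes thus varied between clusters.

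Chromosome shares were taken over UMIs of genes under 500 CPM in both libraries, without mitochondrially encoded and ribosomal protein genes. The share from chromosome 8 fell into 2 groups of cells in both libraries, divided at 5.88%. Low-share cells were 15.6% of wild type cells (14.9 to 16.4) and 44.3% of knockout cells (43.1 to 45.4), with 245 and 210 cells within 0.25 percentage points of the division. When knockout cells were split by the genes on the side of the chromosome nearer its start, genes on the other side had a median log2 ratio of -0.44 between low-share and high-share cells, 129 of 133 of them lower, which argues against a few abundant or co-regulated genes. Median UMIs per knockout cell differed by 1.07-fold between the groups, which argues against depth. A different number of copies of chromosome 8 in part of the cells of both libraries may account for the groups; copy number itself was not measured, and no test here ties it to the knockout.

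Low-share cells made up 74.4% of mesoderm-like knockout cells, against 39.0% of primitive streak-like and 29.8% of naive pluripotent-like knockout cells. They were also 66.7% of knockout and 58.0% of wild type cells in the chaperone-led cluster, and 52.7% of knockout cells in the shallow cluster with mesoderm markers. Chromosome 8 genes as a group were not left out of the clustering genes, so the low share itself may have drawn low-share cells together. A larger part of such cells in the knockout library was weighed as a source of its higher primitive streak genes, but their median log2 ratio was 2.21 within low-share cells and 2.11 within high-share cells. With median-of-ratios size factors that median was 2.14, and the median of all genes moved only from 0.16 to -0.08, a shift too small to give it. After thinning 81.5% of knockout cells kept a T UMI. Median UMIs per cell were close already (20431 in wild type and 20999 in knockout cells). Both tests, on library scaling and on depth, thus had little room to come out otherwise and add little to these values. The test by chromosome 8 share covered primitive streak genes only, not nascent mesoderm genes. Low-share cells were 44.3% of all knockout cells but 74.4% of mesoderm-like ones. Mesp1 was at 341 CPM in low-share, 119.7 CPM in high-share and 220 CPM over all knockout cells. The larger part of low-share cells may thus have added to the mesoderm-like share and to Mesp1. In wild type cells Mesp1 was at 0.711 CPM in low-share and 0.346 CPM in high-share cells. It was therefore higher in the knockout library within each group as well. A difference between the cultures or clones apart from PHD2 stays open, as does the knockout itself, because each group is 1 library.

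Egln1, on chromosome 8, was only 1.33-fold lower in the knockout library. Chromosome 8 dosage alone is argued against as the reason for the lower level, since the log2 ratio was 0.11 in low-share and -0.78 in high-share cells. Nearly all low-share knockout cells being unedited is argued against too: over 18 HIF targets the log2 ratio in low-share cells minus that in high-share cells had a median of -0.0051 (-0.30 to 0.16), with 9 higher and 9 lower. A smaller part of unedited cells could still raise the level. HIF targets in low-share cells had a median log2 ratio of 0.57 (0.10 to 1.04). To argue against unedited cells, the test asked for at least 0.58, set beforehand, and also for a lower limit above the 0.10 found. It met neither, and a median over all low-share cells could not exclude a smaller part in any case. That part cannot be told apart from transcript that persists after the edit, because a median over all low-share cells does not separate edited from unedited cells.

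Over all cells, X had the highest median log2 ratio of the chromosomes, 0.28 (0.17 to 0.34; 150 genes), but it was 0.34 among cells of high and 0.091 among cells of low chromosome 8 share, and in the latter chromosome 11 was higher (0.18). Over all cells the median of X was 0.68 between 40000001 and 50000000 and 0.95 in the next 10 Mb. A high share of chromosome 11 UMIs (above 9.63%) was found in 9.86% of knockout cells and 0.775% of wild type cells, and in knockout cells split by the side nearer its start, genes on the side nearer its end had a median log2 ratio of 0.53. Among 10 Mb windows of chromosome 3, all 14 measured genes between 140000001 and 150000000 were higher in the knockout library (median 0.88), as were all 8 in the next 10 Mb (median 0.62), against a median of 0.14 over the chromosome. Windows were computed over all autosomes and X, and those given here for X and chromosome 3 were chosen after their values were seen.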
